A study of Homo sapiens with 24 samples.

How the data were processed

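Messenger RNA levels were measured on 24 Illumina expression BeadChips, 1 per sample, with biotin-labelled cRNA made from total RNA of SUM159 cells, per the labels' protocols. The labels give 4 siRNA groups of 6 biological replicates each: a control siRNA and siRNAs against exon 1, exon 7 and exon 9 of GNG12-AS1, all at 50 nM, with RNA collected 48 h after transfection. The design text of the series also names HB2 cells, which were not analysed here. One control siRNA product was used throughout, per the labels' protocols.

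The deposited non-normalized table holds log2 intensities per probe with no detection p-values, and its values end at a floor well above 0, as they do where no background has been subtracted. The deposited value table of the same arrays holds log2 intensities after quantile normalization between the 24 arrays, as found by recomputing it: the median absolute difference was 0.00027, and each array's ranks matched with a rank correlation of 1. Its array medians all lie near 7.59. The scale is therefore known from the values. The summarisation program and its version are not given in the sources used here. Of 47231 probes, 4 with missing values (17 values in all) were left out, which left 47227. The platform annotation given with the data named 1 gene for 30110 of these, covering 20045 genes, and several genes for 8 probes, from which no gene was named. The other probes without a listed gene are unnamed here. No probe was annotated to GNG12-AS1.

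From the log2 values, the linear intensities were background-corrected with normexp (offset 50) and quantile-normalized in limma 3.58.1 (R 4.3.3), and log2 values were tested. The design fixed before the data were examined, along with the gene lists, the rule for named genes, the comparisons and the first set of alternatives, called for a filter on detection p-values. None are given, so no filter on detection was applied and all 47227 probes were tested. One linear model over all 24 arrays, with 1 mean per group and no covariate, gave the 7 comparisons through lmFit and eBayes, with Benjamini-Hochberg adjustment over the probes of each comparison and an adjusted p of 0.05 as the threshold. Adjusted p-values named without a test are limma's. Fold changes are log2 differences with their standard errors, and levels are means with standard deviations over 6 arrays. The p-values measure the spread between cultures that the labels call biological replicates. For arrays, their number limits the precision. DIRAS3 was also tested by a two-sided exact permutation test of 6 arrays against 6. A two-sided exact sign-flip test of the locus genes within experiments was added after their values were seen.

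The 29 gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 29 lists and 3 siRNAs (87 tests), and again with an estimated correlation. The list tests between siRNAs, over 4 comparisons, were adjusted together over 116 tests. One probe stood for a gene, the one with the highest mean level over all arrays. Of 844 list entries, 783 had a probe. For lists past the camera threshold with at least 1 siRNA, the list's mean was also compared between siRNA and control within each experiment by a two-sided exact sign-flip test. Those lists were chosen on the same arrays, so this test is no independent check of them. Genes are named by a fixed rule: the genes of the locus, the 8 highest and the 8 lowest log2 fold changes past the threshold for each siRNA against control, 4 members of each list past the threshold, the 5 highest and 5 lowest between siRNAs, and the 10 genes with the largest smallest fold change over the 3 siRNAs in each direction. Symbols that begin with LOC, FLJ, KIAA or MGC, and open reading frame names, are not named. A gene named outside this rule is marked as chosen after its values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

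The sample titles number the experiments, and arrays of one number were taken as pairs across the 4 groups on that basis. Deviations from the group means correlated by 0.171 on average between arrays of 1 number and by -0.0753 between arrays of different numbers, and 27 of 36 same-numbered pairs lay above 0.1. The first principal component of the deviations held 19.6% of their variance, of which the experiment number explained 96.5%. The fit with the replicate number as a block was an alternative. The arrays also fell into 12 brighter and 12 dimmer ones by their median before normalization, with 3 arrays of every group in each. The files name no slide, so this intensity set was used as a block and as a subset instead. Within a set the groups did not come from the same experiments. The control arrays of the brighter set, for example, were replicates 1, 5 and 6, and its exon 1 arrays were replicates 2, 4 and 6. Comparisons within 1 set therefore also hold differences between experiments.

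Alternatives fixed in advance were the deposited normalized values, no background correction, scaling to the 75th percentile, the replicate block, only the arrays compared, eBayes with trend and robust settings, array weights, probes averaged by gene, a fold threshold of 1.5, an adjusted p threshold of 0.01, an estimated correlation, and leaving out each replicate number. Because the 3 siRNAs share 6 control arrays, overlaps and correlations of fold changes were set beside 20 simulations of unchanged groups against shared controls, and recomputed with the controls split between the siRNAs. The simulations and these splits leave out the pairing by experiment, so correlations were also computed, by a choice made after the data were seen, with the 2 siRNAs of a pair taken from separate experiments. A probe was called specific to a group when its level there differed from each of the other 3 groups in the same direction with an adjusted p below the threshold. The test steps were tried on simulated data with 50 changed probes at each of 4 sizes among 47227. In the exon 1, exon 7 and exon 9 comparisons, 46%, 52% and 48% of changes of 0.5 on the log2 scale were recovered, 98%, 96% and 98% of changes of 1, and 6.11%, 8.09% and 5.38% of the calls were false. Changes of 0.25 were recovered in 2%, 2% and 0% of cases. Chromosome and overlap of the locus genes were read from the RefSeq annotation of GRCh38.p14, and no coordinates are given because the array's build is not given in the sources used here.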

Results

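Gene expression was measured in SUM159 cells, an established human breast cancer line, 48 h after transfection with 50 nM of 1 of 4 siRNAs. The siRNAs were a control and 3 siRNAs against exon 1, exon 7 or exon 9 of GNG12-AS1, a long noncoding RNA transcribed from chromosome 1. The series asks whether the RNA product of this gene has functions apart from the act of its transcription, and siRNAs are designed to act on RNA. Neither GNG12-AS1 RNA nor its transcription was assessed here. Each siRNA was used in 6 experiments, called replicates 1 to 6 here, which gave 24 arrays with 6 in each group. Before normalization the median log2 intensity lay between 7.32 and 7.46 on 12 dimmer arrays and between 7.64 and 7.85 on 12 brighter arrays. Each of these sets held 3 arrays of every group. Expression was compared over 47227 probes, of which 30110 named 1 gene.

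No probe was annotated to GNG12-AS1, so its knockdown was not assessed here. Whether any of the 17117 probes without 1 gene symbol reads this RNA was not checked. DIRAS3, an imprinted small GTPase gene with tumour suppressor activity, lies within GNG12-AS1 on chromosome 1, and GNG12 and WLS overlap it. DIRAS3 had a level of 7.32 ± 0.25 (log2 intensity, SD, n = 6) with the control siRNA, 7.50 ± 0.16 with the exon 1 siRNA, 7.35 ± 0.18 with the exon 7 siRNA and 7.44 ± 0.15 with the exon 9 siRNA. Its differences from the control, 0.17 ± 0.11 (SE), 0.02 ± 0.11 and 0.12 ± 0.11, gave exact permutation p of 0.188, 0.87 and 0.355 over arrays and, paired within experiments, exact sign-flip p of 0.125 (higher in 5 of 6), 0.875 (3 of 6) and 0.375 (4 of 6). A second, dimmer DIRAS3 probe differed by 0.10 ± 0.12, 0.18 ± 0.12 and 0.14 ± 0.12 (exact permutation p = 0.435, 0.251 and 0.216). The first and second probes lay at percentiles 61.7 and 40.1 of mean level over all probes. Whether they read above background was not tested. Within the brighter arrays the differences of the first probe were -0.08, -0.11 and -0.14, and within the dimmer arrays 0.43, 0.15 and 0.37, with limma adjusted p from 0.355 to 0.984. Within each set the groups came from partly different experiments, so these values also hold differences between experiments. GNG12, a G protein gamma subunit, differed from the control by 0.20 ± 0.11, 0.18 ± 0.11 and 0.04 ± 0.11, and WLS, which carries WNT proteins to the cell surface, by 0.12 ± 0.13, 0.02 ± 0.13 and 0.10 ± 0.13. Within experiments GNG12 was higher in 5, 6 and 3 of 6 (exact sign-flip p = 0.0938, 0.03125 and 0.656, not adjusted over genes; limma adjusted p = 0.377, 0.519 and 0.93 with the replicate block) and WLS in 5, 4 and 5 of 6 (exact sign-flip p = 0.0938, 0.656 and 0.0938). The stress-induced gene GADD45A varied by 1.13 (SD) within the control group and differed by 0.04 ± 0.48, 0.00 ± 0.48 and -0.12 ± 0.48. These SE come from the fit without pairing and hold the differences between experiments. Within experiments the GADD45A differences had an SD of 0.23, 0.06 and 0.28. They were above 0 in 3, 3 and 2 of 6 experiments (exact sign-flip p = 0.656, 0.906 and 0.375). Adjusted p for these probes of GNG12, WLS and GADD45A lay at or above 0.646 in the 3 comparisons. Of 4 other WLS probes, the one with the smallest p differed by 0.19, 0.05 and 0.14 (exact permutation p = 0.0346, 0.677 and 0.0108; limma adjusted p = 0.592, 0.972 and 0.833). Of the 9 measured genes of the fixed locus list, DEPDC1, named after its values were seen, was lower with the exon 9 siRNA (-0.43 ± 0.11, adjusted p = 0.0442). It was lower in 6 of 6 experiments both with exon 9 and with exon 1 (-0.32 ± 0.11, limma adjusted p = 0.171), with an exact sign-flip p of 0.03125 for each. With exon 7 it differed by 0.07. A second DEPDC1 probe, dim at percentile 3.46, differed by 0.12, 0.05 and -0.09 with exon 1, exon 7 and exon 9. Whether the fall of DEPDC1 has to do with its place in the locus list was not tested.

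The labels could be checked through the RNAs that 1 siRNA lowered below all 3 other groups. For each array the low probes were found without the arrays of its replicate number. The exon 1 set thus held 28, 19, 15, 98, 37 and 18 probes for replicates 1 to 6. On a scale from 0 (mean of the other groups) to 1 (mean of the siRNA's own group), 23 arrays had their own group's low probes at a median of 0.707 to 1.25 and those of other siRNAs at -0.221 to 0.178. The array labelled exon 9 replicate 4 had the low probes of the exon 1 group at 1.05, with 96 of 98 probes past the midpoint, and those of the exon 9 group at 0.41, with 14 of 46 past it. CA12, a membrane carbonic anhydrase, stood at 10.45 on this array and at 11.82 to 12.03 on the 5 other exon 9 arrays, against a mean of 10.43 ± 0.29 with the exon 1 siRNA (SD, n = 6). The array was kept in its labelled group, so directions drawn from the exon 9 group include it. Leaving it out changed the values given below.

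**Figure D1:**
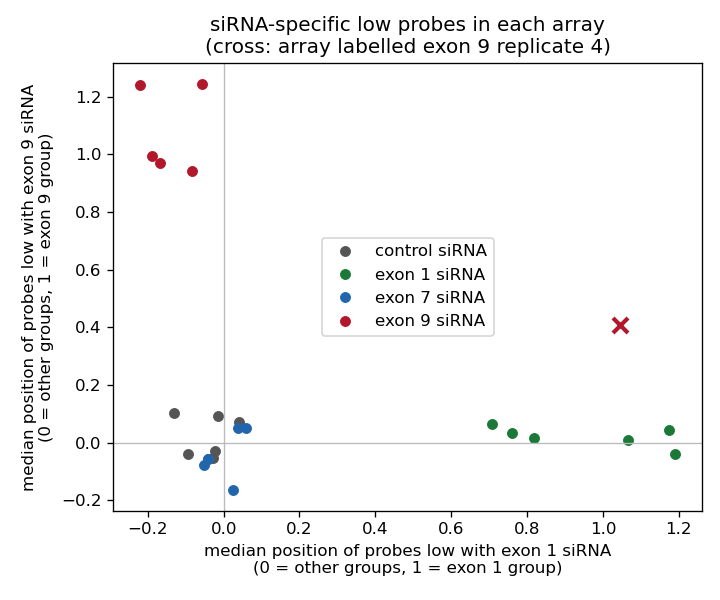
Each point is 1 of the 24 arrays. The horizontal axis gives the median position of probes low with the exon 1 siRNA, and the vertical axis that of probes low with the exon 9 siRNA. On both axes 0 is the mean of the other groups and 1 the mean of the siRNA's own group. Probes and means were found for each array without the arrays of its replicate number, so the probe sets differ between replicates. The array labelled exon 9 replicate 4, drawn as a cross, sits at 1.05 and 0.41, apart from the other 23.

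The siRNA against exon 1 was compared with the control siRNA to ask what its use changed. CLDN1, a tight junction protein, rose by 1.71 ± 0.33 (log2, SE, 6 arrays against 6, adjusted p = 0.00306), and PTPMT1, a mitochondrial phosphatase of cardiolipin synthesis, rose by 1.62 ± 0.09 (adjusted p = 1.08e-12) from 9.75 ± 0.23 (SD). LZTFL1, a regulator of ciliary trafficking, rose by 1.27 ± 0.10, RBPJ, the DNA-binding factor of Notch signalling, by 1.19 ± 0.10, and TOMM20, a receptor for mitochondrial protein import, by 1.11 ± 0.09. TMEFF2 (1.23 ± 0.18), the glucose transporter SLC2A3 (1.14 ± 0.18) and ID3 (1.06 ± 0.18), an inhibitor of basic helix-loop-helix factors, completed the 8 highest, with adjusted p of 0.000425 or less. SERPINB3 fell by 1.80 ± 0.24 on the log2 scale and its close paralog SERPINB4 by 1.43 ± 0.25, both protease inhibitors; whether each probe reads its own gene alone was not tested. SCML1, a Polycomb-like protein, fell by 1.79 ± 0.15 (adjusted p = 1.97e-09), CA12 fell by 1.46 ± 0.18 (adjusted p = 9.73e-06) and CCP110, a centriole protein that restrains cilium assembly, fell by 1.28 ± 0.15. CPED1 (-1.41 ± 0.19), the acute-phase gene SAA2 (-1.35 ± 0.28) and FAM117B (-1.26 ± 0.15) were the others of the 8 lowest, with adjusted p between 6.65e-06 and 0.00589. Several of these genes had dimmer probes that moved less: the other probes of RBPJ gave 0.33 and 0.29, those of SCML1 -0.73 and -0.18, and those of CPED1 -0.30 and -0.23, while that of TOMM20 gave 1.17.

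In all, 650 probes (465 genes) passed an adjusted p of 0.05 with the exon 1 siRNA, 340 higher and 310 lower, and 259 of them changed by at least 1.5-fold. With the replicate number as a block 1522 probes passed, which included 649 of the 650, and with the intensity set as a block 696 passed. The brighter arrays alone gave 133 (64 higher and 69 lower) and the dimmer arrays alone 110 (84 and 26), with 3 arrays against 3. SAA2 lost its call without replicate 3 (adjusted p = 0.0507), and NETO2, NASP, ATAD2, BAMBI, RIPOR2, PTPN14 and ASNSD1 gained one with the replicate block (adjusted p from 0.000728 to 0.0373). PTPN14 also passed without the array labelled exon 9 replicate 4 (adjusted p = 0.044).

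A few genes of the cell cycle fell with the exon 1 siRNA. Of 47 G2 and M phase genes, 4 fell and 0 rose (6 adjusted over the list alone): the chromosome condensin subunit SMC4 by -0.97 ± 0.11, the mitotic kinase AURKA by -0.74 ± 0.11, the kinase partner CKS1B by -0.71 ± 0.13 and the kinetochore protein CENPF by -0.44 ± 0.10 (adjusted p from 2.9e-06 to 0.0126). The other SMC4 probes differed by -0.79 and 0.12. The list's median log2 fold change was -0.13 (camera adjusted p = 3.52e-06, or 0.829 with an estimated correlation). With the replicate block these camera values were 1.48e-07 and 0.298. Of 50 S phase genes, the DNA repair genes USP1 (-0.48 ± 0.09) and RAD51AP1 (-0.51 ± 0.12) fell, with 3 adjusted over the list alone, while ATAD2 (-0.47 ± 0.14, adjusted p = 0.11) and NASP (-0.41 ± 0.13, adjusted p = 0.158) did not pass. This list had a median of -0.15 (camera adjusted p = 0.000369, or 0.862 with an estimated correlation). With the replicate block its camera values were 1.48e-07 and 0.287. Both lists had a lower mean in 6 of 6 experiments (exact sign-flip p = 0.03125, the smallest 6 pairs allow). In the brighter arrays the medians were -0.27 for G2 and M phase and -0.32 for S phase, and in the dimmer arrays -0.01 and 0.03. The sets are not matched by experiment. Replicate 2, which had the lowest mean of both lists, lay in the brighter set for exon 1 and in the dimmer set for the control. RAD51AP1 lost its call without replicates 1, 2, 3, 5 or 6 in turn (adjusted p of 0.057 to 0.124) and CENPF without replicates 2, 3 or 6 (0.0731 to 0.103).

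Of 40 genes of cell migration and focal adhesion, 4 rose and 1 fell with the exon 1 siRNA (5 adjusted over the list alone). The GTPase RHOB rose by 0.78 ± 0.16, the matrix protease MMP3 by 0.66 ± 0.15 and the focal adhesion protein PARVA by 0.60 ± 0.10, while the collagen receptor subunit ITGA2 fell by 0.52 ± 0.10 (adjusted p from 0.000314 to 0.0163). The focal adhesion kinase PTK2 lay just past the threshold (0.36, adjusted p = 0.0489) and lost its call without any 1 of the 6 replicates (0.0988 to 0.192) and with a normexp offset of 16 (0.0861). The other probes of PARVA and PTK2 differed by 0.29 and 0.12. MMP3 lost its call without replicates 1, 3, 4 or 5 in turn (0.0603 to 0.0887). The list's median was 0.10 (camera adjusted p = 0.0102; adjusted p = 0.829 with an estimated correlation), and its mean was higher in 6 of 6 experiments (exact sign-flip p = 0.03125). The camera call was lost without replicate 3 (0.052) or replicate 5 (0.0514), and the medians were 0.04 in the brighter and 0.16 in the dimmer arrays.

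The siRNA against exon 7 was compared with the control siRNA in the same way. PTPMT1 rose by 1.63 ± 0.09 (adjusted p = 9.67e-13), RBPJ by 1.14 ± 0.10 and LZTFL1 by 1.06 ± 0.10. PPP3CB, a catalytic subunit of calcineurin, rose by 0.95 ± 0.09, the calcium-binding proteins PDCD6 and CALU by 0.94 ± 0.08 and 0.94 ± 0.09, the stress granule protein G3BP2 by 0.94 ± 0.10 and the phospholipid flippase ATP9A by 0.93 ± 0.15 (adjusted p of 0.000824 or less for all). SERPINB4 fell by 1.53 ± 0.25 and SERPINB3 by 1.27 ± 0.24. JOSD1, a deubiquitinase, fell by 1.30 ± 0.10 (adjusted p = 3.02e-09), and AKT1, the survival kinase, fell by 1.12 ± 0.11 from 11.33 ± 0.18 (SD, n = 6, adjusted p = 2.87e-07). NETO2 (-1.09 ± 0.21), the selenoprotein SELENOT (-1.04 ± 0.15) and the protein kinase C gene PRKCA (-0.69 ± 0.10) were also among the lowest 8, and CSRNP1 fell by 1.00 ± 0.15. AKT1 fell by 1.24 on a second probe and differed by 0.09 on another, dim probe, and the other probe of SELENOT differed by -0.11. The other, dim probes of ATP9A differed by 0.02 and 0.08.

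With the exon 7 siRNA 269 probes (199 genes) passed, 177 higher and 92 lower, and 96 of them by at least 1.5-fold. All 269 were among the 814 of the replicate block, and the intensity set block gave 313. The brighter arrays alone gave 13 (9 higher and 4 lower) and the dimmer arrays alone 31 (24 and 7). CLDN1 gained a call with the replicate block (0.90, adjusted p = 0.397 without and 0.00218 with it), as did RHOB, ITGA3, CD44 and AIDA. NETO2 lost its call without replicate 3 (adjusted p = 0.0526).

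Of the 40 migration and adhesion genes, PARVA (0.66 ± 0.10, adjusted p = 0.00021) and PTK2 (0.49 ± 0.10, adjusted p = 0.00619) rose with the exon 7 siRNA and 0 fell, with 7 adjusted over the list alone. The other probes of PARVA and PTK2 differed by 0.14 and 0.14. The integrin ITGA3 (0.40 ± 0.11, adjusted p = 0.0861) and the hyaluronan receptor CD44 (-0.34 ± 0.09, adjusted p = 0.0992) did not pass. The list's median was 0.08 (camera adjusted p = 0.0154; adjusted p = 0.829 with an estimated correlation), its mean was higher in 6 of 6 experiments (exact sign-flip p = 0.03125), and the camera call was lost without replicate 3 (0.052) or replicate 5 (0.0716). PTK2 lost its call without replicate 6 (0.0581). Of 24 target genes of the transcription factors YAP and TEAD, the phosphatase PTPN14 rose (0.51 ± 0.11, adjusted p = 0.0139), with 2 adjusted over the list alone. It was the list's only called member and lost its call without replicate 1 (0.0579), 3 (0.0891) or 5 (0.101). ANKRD1 (0.29 ± 0.08), WWC1 (0.24 ± 0.10) and FSTL1 (0.30 ± 0.12) had adjusted p from 0.134 to 0.512. This list's median was 0.15 (camera adjusted p = 0.0403; adjusted p = 0.829 with an estimated correlation), with a higher mean in 6 of 6 experiments (exact sign-flip p = 0.03125). Its camera call was lost without replicates 1, 4, 5 or 6 in turn (0.0504 to 0.0779) and with a normexp offset of 16 (0.0572). Medians within the brighter and dimmer arrays were 0.04 and 0.09 for migration and 0.21 and 0.12 for the YAP and TEAD targets.

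For the siRNA against exon 9, compared with the control siRNA, the growth factor FGF2 fell most, by 1.44 ± 0.17 to 7.48 ± 0.37 (SD, n = 6, adjusted p = 5.98e-06). The cell cycle kinase CDK6 fell by 1.07 ± 0.15, SCML1 by 1.03 ± 0.15 and CCDC59 by 1.00 ± 0.14. MTOR, the growth-regulating kinase, fell by 0.98 ± 0.09 (adjusted p = 3.52e-08), the p53-binding protein TP53BP2 by 0.93 ± 0.13, METAP1, which removes initiator methionines, by 0.88 ± 0.09 and ASNSD1 by 0.85 ± 0.12 (adjusted p of 0.000124 or less). PTPMT1 rose by 1.62 ± 0.09 (adjusted p = 1.09e-12), LZTFL1 by 1.18 ± 0.10, TOMM20 by 1.08 ± 0.09, RBPJ by 1.05 ± 0.10 and PDCD6 by 0.97 ± 0.08. The actin-binding protein MARCKSL1 rose by 0.95 ± 0.16, BANF1, which binds chromatin at the nuclear envelope, by 0.94 ± 0.09 and ISOC1 by 0.92 ± 0.11. Weaker second probes of FGF2 and TP53BP2 differed by -0.20 and -0.11.

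With the exon 9 siRNA 313 probes (245 genes) passed, 195 higher and 118 lower, and 137 of them by at least 1.5-fold. All 313 were among the 795 of the replicate block, and the intensity set block gave 345. The brighter arrays alone gave 59 (27 higher and 32 lower) and the dimmer arrays alone 64 (54 and 10). Without the array labelled exon 9 replicate 4, 311 probes passed, PARVA (adjusted p = 0.0556) and ITGA2 (0.0828) lost their calls, and ATP9A (0.67, adjusted p = 0.0178) gained one. PARVA also lost its call without replicates 2 to 6 in turn (0.0599 to 0.166) and ITGA2 without any 1 replicate but 5 (0.0776 to 0.244). TMEFF2, SLC2A3, ID3, CLDN1 and SERPINB3 gained calls with the replicate block (adjusted p from 0.000237 to 0.0289), and without a block TMEFF2 passed when replicate 2 was left out (0.00528) and SLC2A3 when replicate 6 was (0.0318).

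Of the 47 G2 and M phase genes, 0 passed with the exon 9 siRNA over all probes in limma, 4 adjusted over the list alone and 10, all lower, at an unadjusted p under 0.05. The chromatin protein HMGB2 (-0.53 ± 0.13, adjusted p = 0.0539), SMC4 (-0.45 ± 0.11, adjusted p = 0.0577), the hyaluronan-binding spindle protein HMMR (-0.38 ± 0.11, adjusted p = 0.134) and AURKA (-0.35 ± 0.11, adjusted p = 0.249) had the smallest p. HMGB2, SMC4 and HMMR passed with the replicate block (0.00294, 0.0253 and 0.0202), and HMGB2 passed without the array labelled exon 9 replicate 4 (-0.60, adjusted p = 0.0169). The list's median was -0.10 (camera adjusted p = 0.000134; adjusted p = 0.829 with an estimated correlation), and its mean was lower in 6 of 6 experiments (exact sign-flip p = 0.03125). The median was -0.17 in the brighter and -0.02 in the dimmer arrays.

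The 3 siRNAs share 1 target, so probes that moved in the same direction with all of them were counted. PTPMT1 rose to nearly the same level with each: 11.37 ± 0.10 with exon 1, 11.38 ± 0.08 with exon 7 and 11.37 ± 0.08 with exon 9 (SD, n = 6), against 9.75 ± 0.23 with the control. MET, the receptor for hepatocyte growth factor, rose from 9.07 ± 0.16 to 9.92 ± 0.16, 9.99 ± 0.18 and 9.89 ± 0.17, by 0.85 ± 0.10, 0.92 ± 0.10 and 0.82 ± 0.10 (SE, adjusted p of 1.24e-05 or less). The stress-activated kinase MAP3K20 rose by 0.86 ± 0.10, 0.78 ± 0.10 and 0.90 ± 0.10, the ubiquitin ligase component WSB1 by 0.96 ± 0.13, 0.77 ± 0.13 and 0.92 ± 0.13, and G3BP2 by 0.93 ± 0.10, 0.94 ± 0.10 and 0.87 ± 0.10. PSG4, of a family of close paralogs, rose by 1.02 ± 0.13, 0.80 ± 0.13 and 0.76 ± 0.13, although its other probes gave 0.26 to 0.36 and 0.10 to 0.19. PTPMT1, LZTFL1, RBPJ, PDCD6 and TOMM20 were the other 5 of the 10 genes with the largest shared rise. Other MAP3K20 probes differed by 0.38, 0.38 and 0.42 and by -0.09, -0.09 and 0.02.

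Of 47227 probes, 84 (58 named genes) were higher with all 3 siRNAs, 1 was lower and 1 moved in opposite directions. No named gene was lower with all 3 in limma, while 85 genes were lower with each at an unadjusted p under 0.05. At that unadjusted threshold 165 probes were lower and 418 higher with all 3. No chance value with shared controls was computed for it, so the 85 genes are not read as a shared fall. For calls at the adjusted threshold, independent lists of the same sizes would share 0.00526 probes higher and 0.00151 lower. At that adjusted threshold, 20 simulations of unchanged groups against shared controls, without the pairing, gave 0 of either. No probe was changed in these simulations, so hardly any could be called. They do not show how far shared controls raise the overlap of called probes. With the 6 controls divided so that each siRNA had 2 of its own, in 15 ways, 13 to 19 probes were higher with all 3 (median 16) and 0 were lower. Fewer controls for each siRNA also lower the power to call a probe. The fall from 84 therefore does not measure what shared controls add. Among the 84 probes, 3 differed between any 2 of the siRNAs, and the median log2 fold change was 0.65. The replicate block gave 177 higher and 26 lower, and the intensity set block 92 higher, while the brighter arrays alone gave 5 probes and the dimmer arrays alone 18.

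**Figure D2:**
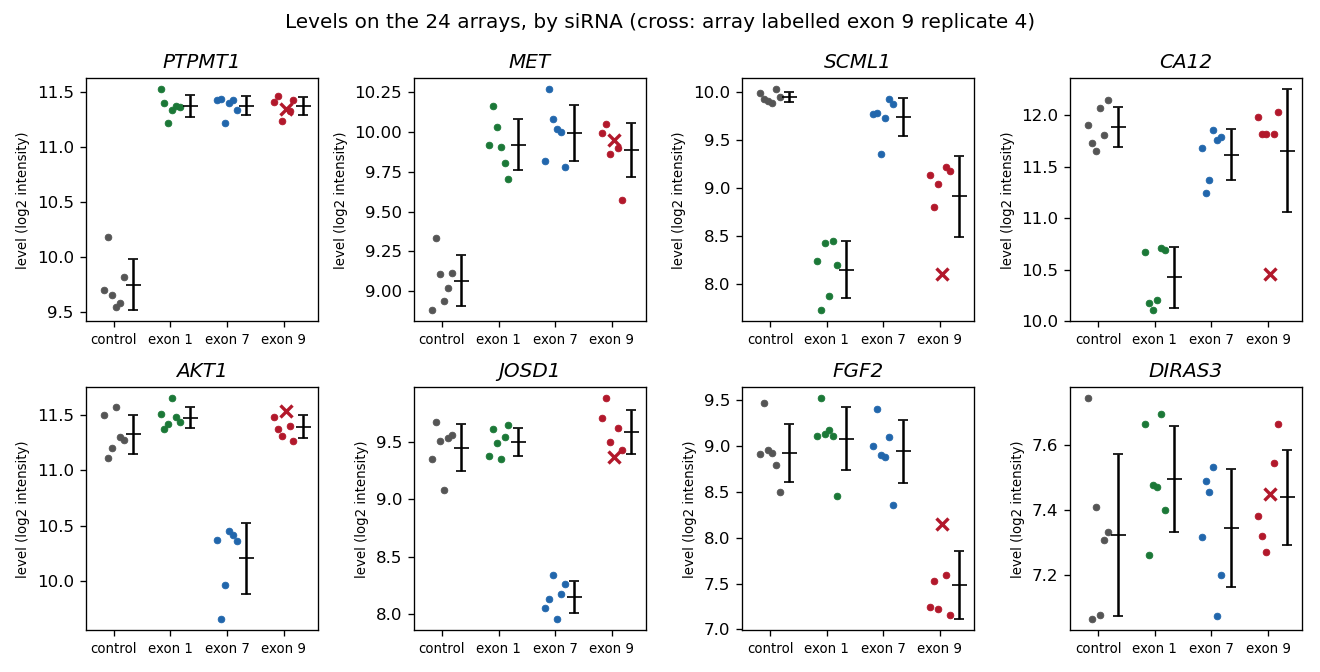
Level (log2 intensity) of 8 genes on each of the 24 arrays, grouped by siRNA on the horizontal axis, with the mean ± SD of the 6 arrays beside the points and the array labelled exon 9 replicate 4 as a cross. PTPMT1 and MET were higher with all 3 siRNAs, while SCML1 and CA12 were lowest with exon 1, AKT1 and JOSD1 with exon 7 and FGF2 with exon 9.

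Fold changes of the siRNAs were also compared across all 47227 probes, which are not independent replicates. Against the shared controls Pearson's r was 0.472 between exon 1 and exon 7, 0.546 between exon 1 and exon 9 and 0.478 between exon 7 and exon 9, and shared controls alone bring r to 0.50 in a simulation of unchanged groups that leaves out the pairing by experiment. With the 2 siRNAs taken from separate experiments, each against the controls of its own experiments, in 10 ways, r averaged 0.113 (0.0425 to 0.135 over the splits), 0.154 (0.0806 to 0.179) and 0.0930 (0.0213 to 0.112). Without the 84 shared probes it averaged 0.0902 (0.0192 to 0.113), 0.132 (0.0578 to 0.157) and 0.0702 (-0.00205 to 0.0895). Without replicate 4 it averaged 0.105 (0.0384 to 0.141), 0.0881 (0.0214 to 0.128) and 0.0617 (-0.00916 to 0.0941). Splitting the 6 controls 3 and 3 under all 6 arrays of each siRNA gave 0.0711 (-0.0931 to 0.130), 0.130 (-0.0403 to 0.191) and 0.0517 (-0.115 to 0.112), but differences between experiments enter these values with opposite signs. Leaving out the array labelled exon 9 replicate 4 moved the r of exon 1 and exon 9 against the shared controls to 0.477.

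The siRNAs were compared with each other to ask where agents against 1 RNA differ, without the controls. JOSD1 (1.35 ± 0.10), AKT1 (1.27 ± 0.11, adjusted p = 4.08e-08) and SELENOT (1.18 ± 0.15) were higher with exon 1 than with exon 7, followed by the BMP antagonist BAMBI (1.06 ± 0.22) and TMEFF2 (1.04 ± 0.18). SAA2 (-1.60 ± 0.28), SCML1 (-1.59 ± 0.15), PLEKHA3 (-1.24 ± 0.16), a lipid-binding Golgi protein, RIPOR2 (-1.24 ± 0.26) and CA12 (-1.19 ± 0.18) were lower. In total 577 probes differed between these siRNAs, 229 higher and 348 lower with exon 1. The G2 and M phase list had a median of -0.18 (camera adjusted p = 2.56e-09; adjusted p = 0.802 with an estimated correlation), the S phase list -0.13 (0.000879; adjusted p = 0.85 with an estimated correlation) and the NRF2 list -0.10 (0.0289; adjusted p = 0.802 with an estimated correlation). The replicate block gave 1525 probes and the intensity set block 628, against 68 in the brighter (14 higher and 54 lower) and 10 in the dimmer arrays (8 and 2). Without replicate 2 RIPOR2 lost its call (adjusted p = 0.0688), and without replicate 3 BAMBI did (0.127).

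FGF2 (1.60 ± 0.17, adjusted p = 6.31e-06), the sulfatase ARSJ (1.12 ± 0.11), TP53BP2 (1.10 ± 0.13), the histone acetyltransferase KAT2B (0.97 ± 0.13) and YRDC (0.91 ± 0.12), a tRNA-modifying protein, were higher with exon 1 than with exon 9. FAM117B (-1.30 ± 0.15), CA12 (-1.23 ± 0.18), SERPINB3 (-1.05 ± 0.24), CCP110 (-0.93 ± 0.15) and the heat shock protein HSPA14 (-0.93 ± 0.20, lower in 5 of 6 experiments) were lower. Between these siRNAs 219 probes differed, 114 higher and 105 lower with exon 1, and 433 without the array labelled exon 9 replicate 4. The S phase list had a median of -0.14 (camera adjusted p = 0.000878; adjusted p = 0.85 with an estimated correlation). With these blocks 746 (replicate number) and 243 (intensity set) probes differed, against 85 in the brighter arrays (39 higher and 46 lower) and 1, higher, in the dimmer arrays, which hold the array labelled exon 9 replicate 4. SERPINB3 lost its call without replicates 2, 3, 5 or 6 in turn (adjusted p of 0.053 to 0.3), and HSPA14 without replicates 1, 2, 3 or 6 (0.0891 to 0.296).

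FGF2 (1.46 ± 0.17), AIDA (1.10 ± 0.11), TP53BP2 (1.07 ± 0.13), ARSJ (0.93 ± 0.11) and CCDC59 (0.91 ± 0.14) were higher with exon 7 than with exon 9, with adjusted p of 0.000228 or less. JOSD1 (-1.43 ± 0.10, adjusted p = 5.04e-10), AKT1 (-1.19 ± 0.11), NETO2 (-1.11 ± 0.21), SMAP1 (-1.05 ± 0.10), which regulates clathrin-dependent endocytosis, and SELENOT (-0.92 ± 0.15) were lower. SMAP1 was read by 2 probes that moved apart with exon 7 against the control (-0.45 and 0.49). Between these siRNAs 270 probes differed, 153 higher and 117 lower with exon 7. The lists past the threshold had positive medians: G2 and M phase (0.19, camera adjusted p = 6.23e-07; adjusted p = 0.802 with an estimated correlation), hypoxia and glycolysis (0.08, 0.0236; adjusted p = 0.847 with an estimated correlation) and NRF2 targets (0.13, 0.0121; adjusted p = 0.802 with an estimated correlation). Blocks of replicate number and of intensity set gave 1039 and 306 probes, against 37 in the brighter (30 higher and 7 lower) and 23 in the dimmer arrays (12 and 11). NETO2 lost its call without replicate 3 (adjusted p = 0.0567).

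The exon 1 siRNA was also set against the mean of the exon 7 and exon 9 siRNAs. BAMBI (0.94 ± 0.19), SPOCD1 (0.91 ± 0.17), FGF2 (0.87 ± 0.15), TMEFF2 (0.81 ± 0.16) and PGM2L1 (0.74 ± 0.14), a sugar phosphate enzyme, were higher. SAA2 (-1.29 ± 0.24), CA12 (-1.21 ± 0.16), SCML1 (-1.18 ± 0.13, adjusted p = 9.07e-06), FAM117B (-1.13 ± 0.13) and PLEKHA3 (-1.08 ± 0.14) were lower. The difference in FGF2 came with a level of 9.08 ± 0.35 with exon 1, 8.94 ± 0.34 with exon 7 and 7.48 ± 0.37 with exon 9 (SD, n = 6). In this comparison 409 probes passed, 141 higher and 268 lower, with the S phase list at a median of -0.13 (camera adjusted p = 8.39e-05; adjusted p = 0.847 with an estimated correlation) and the G2 and M phase list at -0.08 (3.11e-05; adjusted p = 0.802 with an estimated correlation). The replicate block gave 1154 probes and the intensity set block 431. The brighter arrays gave 107 (16 higher and 91 lower), and the dimmer arrays gave 0 in limma with 2772 at an unadjusted p under 0.05. BAMBI (0.161), TMEFF2 (0.0877) and SAA2 (0.0599) lost their calls without replicate 3, and BAMBI also without replicate 2 (0.0546).

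Probes were then counted that set 1 group apart from each of the other 3. The exon 1 group had 72 such probes lower and 8 higher, with SCML1, CA12, FAM117B, CPED1 and PLEKHA3 among the lower. The exon 7 group had 34 lower and 9 higher, with JOSD1, AKT1, SELENOT, CSRNP1 and PRKCA lower, and the exon 9 group had 43 lower and 2 higher, with FGF2, TP53BP2, ARSJ, MTOR and METAP1 lower. In the control group 84 were lower and 1 higher. Without the array labelled exon 9 replicate 4, the lower and higher counts became 134 and 14 for exon 1, 34 and 7 for exon 7, 61 and 2 for exon 9 and 77 and 2 for the control. Of the probes lower than the control with at least 1 siRNA, 33 of 486 were lower with at least 2, and of those higher, 176 of 452 were higher with at least 2. These counts come from the fit without a block. With the replicate block 26 probes were lower and 177 higher with all 3 siRNAs, against 1 and 84 without it. By pair (exon 1 and exon 7, exon 1 and exon 9, exon 7 and exon 9) the shared lower probes numbered 9, 24 and 2, against 0.604, 0.775 and 0.230 for independent lists, and 11, 19 and 3 without the array labelled exon 9 replicate 4. The shared higher probes numbered 108, 140 and 96, against 1.27, 1.40 and 0.731. The comparisons of a pair share their control arrays, so independent lists are not the value to expect without a change. Sharing by pairs was not simulated.

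The other fixed lists were tested with the 3 siRNAs in the same order, exon 1, exon 7 and exon 9. Over all 47227 probes, 4511, 3678 and 3529 had an unadjusted limma p under 0.05. List counts near that share show no change particular to a list. The share among the probes that stand for 1 gene was not computed. Of 33 genes of MET receptor signalling, 4, 2 and 4 passed (6, 4 and 4 adjusted over the list alone), and MET and the phosphatase PTPN1 rose with each siRNA; camera gave adjusted p of 0.117, 0.153 and 0.9. The p53 target CDKN1A, a cell cycle inhibitor, rose by 0.63 ± 0.11 and 0.65 ± 0.11 with exon 1 and exon 7 and differed by 0.30 with exon 9; it was chosen after its values were seen, as were PTPN1, SNAI2 and ANKRD1 in this paragraph. Of 27 p53 targets 2, 1 and 0 passed (3, 2 and 1 adjusted over the list alone; 6 with exon 9 at an unadjusted p under 0.05; camera adjusted p = 0.192, 0.924 and 0.9). Among epithelial-mesenchymal transition genes, CLDN1 and the transcription factor SNAI2 rose with exon 1 (2 of 21, and 2 adjusted over the list alone) and 0 passed with exon 7 or exon 9, with 1 and 3 at an unadjusted p under 0.05 (0.426, 0.452 and 0.352). With the replicate block CLDN1 also passed with exon 7 and exon 9 (limma adjusted p = 0.00218 and 0.0083). ANKRD1 rose with exon 1 (0.81 ± 0.08) and with exon 9 (0.50 ± 0.08), and the YAP and TEAD list gave 0.153 with exon 1 and 0.295 with exon 9 (3 members each adjusted over the list alone), its mean being higher in 6 of 6 experiments with exon 1 (0.10, exact sign-flip p = 0.03125) and in 4 of 6 with exon 9 (0.3125). Migration and adhesion genes gave 0.117 with exon 9 (3 called, 4 adjusted over the list alone; 0.031 without replicate 6; mean higher in 4 of 6 experiments), S phase genes 0.868 with exon 7 and 0.727 with exon 9 (1 each adjusted over the list alone), and G2 and M phase genes 0.452 with exon 7 (0 in limma, 1 at an unadjusted p under 0.05).

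Several lists had 1 to 2 called members with at least 1 siRNA. In apoptosis regulators 2, 0 and 0 of 32 passed (2, 1 and 1 adjusted over the list alone; 6, 3 and 5 at an unadjusted p under 0.05), with camera adjusted p of 0.212, 0.336 and 0.86, and in immediate early genes 2, 0 and 0 of 34 (6, 2 and 0; 8, 3 and 6), with 0.231, 0.974 and 0.943. Cholesterol synthesis genes had 1, 0 and 0 of 27 called in limma, 9, 0 and 1 adjusted over the list alone and 9, 0 and 4 at an unadjusted p under 0.05 (0.231, 0.75 and 0.9). For TGF-beta targets the values were 1, 0 and 1 of 22 (1, 0 and 2; 3, 1 and 3; 0.246, 0.854 and 0.697), for hypoxia and glycolysis 1, 0 and 0 of 32 (2, 2 and 2; 5, 6 and 3; 0.452, 0.072 and 0.75) and for NRF2 targets 1, 1 and 0 of 25 (1, 1 and 0; 7, 3 and 5; 0.214, 0.426 and 0.151), in the same order of counts. Extracellular matrix genes had 0, 1 and 0 of 32 (4, 1 and 0; 9, 3 and 2; 0.117, 0.284 and 0.305) and the stress and unfolded protein response 0, 0 and 1 of 37 (1, 1 and 1; 4, 3 and 2; 0.995, 0.75 and 0.153). Heat shock proteins had 1, 0 and 0 of 23 (1, 0 and 0; 5, 2 and 1; 0.598, 0.9 and 0.706), RNAi machinery 1, 0 and 0 of 20 (1, 0 and 0; 2, 0 and 3; 0.231, 0.9 and 0.509), ribosomal proteins 1, 1 and 0 of 41 (1, 1 and 0; 3, 4 and 1; 0.694, 0.284 and 0.862) and luminal epithelial markers 0, 1 and 0 of 18 (0, 2 and 0; 0, 3 and 1; 0.772, 0.151 and 0.706). The locus list had 0, 0 and 1 of 9 (1, 0 and 1; 2, 0 and 1; 0.75, 0.706 and 0.706).

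No member was called in limma with any siRNA in 9 lists. Their unadjusted counts are to be read beside 4511, 3678 and 3529 of all 47227 probes. At an unadjusted p under 0.05 the counts with exon 1, exon 7 and exon 9 were 5, 6 and 4 of 43 interferon response genes, 4, 2 and 3 of 30 NF-kappaB targets, 4, 0 and 1 of 17 WNT targets, 3, 2 and 0 of 38 oxidative phosphorylation genes and 2, 2 and 0 of 17 histones. They were 6, 1 and 1 of 12 fibroblast markers, 1, 1 and 0 of 13 blood and immune markers, 0 of 8 basal epithelial markers with each siRNA, and 2, 1 and 1 of 11 housekeeping genes. Adjusted over the list alone, 2, 1 and 0 NF-kappaB targets, 3, 0 and 0 fibroblast markers and 1, 0 and 1 housekeeping genes passed, and 0 of the others. Camera adjusted p were 0.727, 0.882 and 0.165 for interferon response, 0.706, 0.188 and 0.151 for NF-kappaB, 0.706, 0.504 and 0.9 for WNT, 0.75, 0.151 and 0.631 for oxidative phosphorylation and 0.945, 0.284 and 0.554 for histones. They were 0.151, 0.686 and 0.151 for fibroblast, 0.771, 0.882 and 0.698 for blood and immune, 0.151, 0.75 and 0.151 for basal epithelial markers, and 0.284, 0.706 and 0.706 for housekeeping genes. Across the fixed lists, median and mean differed in sign for several near 0, such as p53 targets with exon 9 (median 0.02, mean -0.05).

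Over the 29 lists and 3 siRNAs, 6 camera tests passed at the preset correlation and 0 of 87 with an estimated correlation, where 5 had an unadjusted p under 0.05. With the replicate block 17 passed. The lists added were extracellular matrix and fibroblast markers (higher), and NRF2 targets and basal epithelial markers (lower), with exon 1 (adjusted p = 0.0445, 0.0132, 0.0392 and 0.0194). With exon 7 they were hypoxia and glycolysis (higher, 0.00264) and NF-kappaB targets (lower, 0.0132). With exon 9 they were fibroblast markers (higher, 0.0172), the stress and unfolded protein response (lower, 1.43e-06), NF-kappaB targets (lower, 0.00307), NRF2 targets (lower, 0.01) and basal epithelial markers (lower, 0.0495). None passed with both the block and an estimated correlation (14 had an unadjusted p under 0.05). For the 6 tests that passed without a block, the camera adjusted p with both lay between 0.194 and 0.38. Without a block the estimated correlation also holds differences between experiments. Of 100 random regroupings of the 24 arrays, the real one included, 82 gave at least 6 lists past the threshold, and of 50 that kept arrays of an experiment together 3 did.

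**Figure D3:**
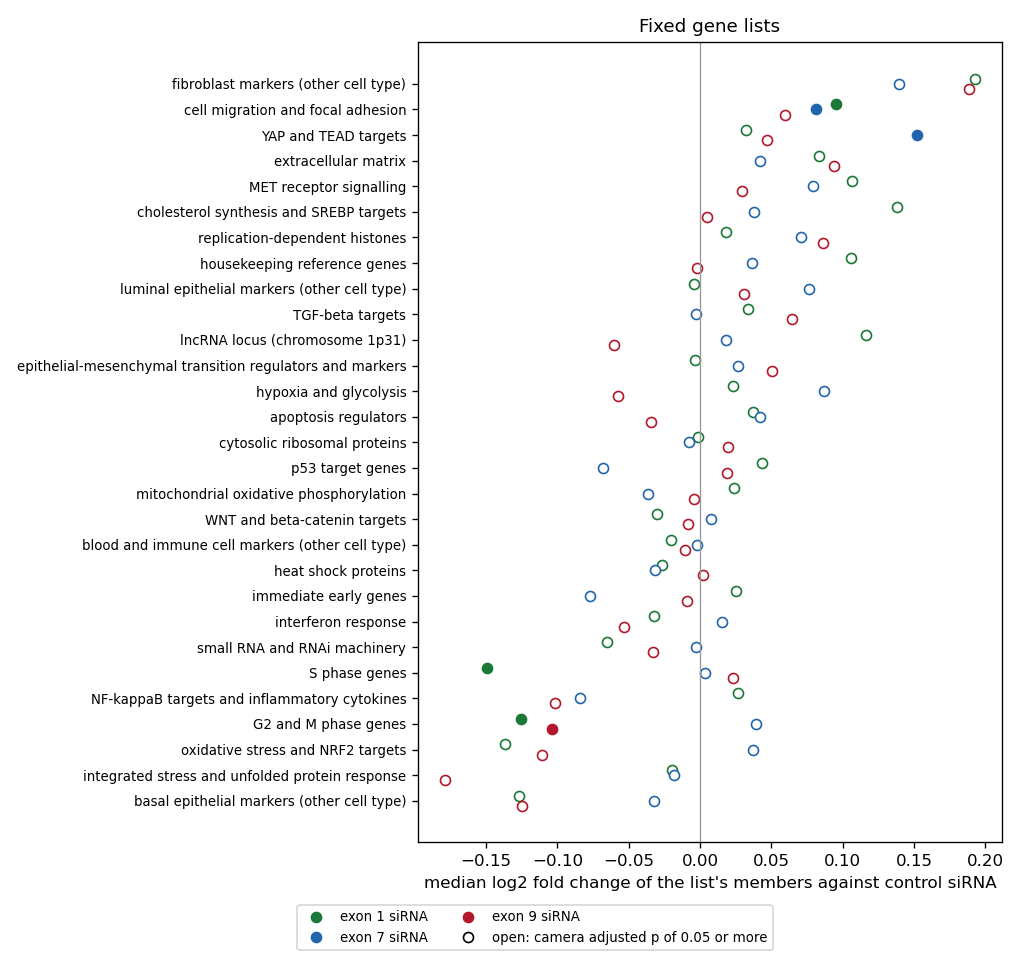
Median log2 fold change of each fixed list's members against the control siRNA, 3 points for each list (exon 1, exon 7 and exon 9 siRNA), filled where the camera adjusted p at the preset correlation was below 0.05. Filled points are migration and focal adhesion with exon 1 (0.10) and exon 7 (0.08), YAP and TEAD targets with exon 7 (0.15), S phase with exon 1 (-0.15) and G2 and M phase with exon 1 (-0.13) and exon 9 (-0.10).

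Each gene named by the fixed rule and past the threshold moved in the direction given in 6 of 6 experiments, apart from HSPA14. These genes were chosen for their changes on the same arrays, so this agreement is no independent check.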

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

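Of the explanations weighed in this part, the tests of a wrong label and of uptake of both siRNAs were chosen after the result was seen, and the test of mixed RNA before it. Values were marked where 1 array stood apart from the other 5 of its group by Dixon's ratio, which marks about 1 in 20 groups by chance. Among 308 groups of 6 values for the named genes, 22 (7.14%) were marked, and 11 of them were on the array labelled exon 9 replicate 4.

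On that array, levels lay below the range of the other 5 exon 9 arrays for CA12 (10.45 against 11.82 to 12.03), CPED1 (9.825 against 11.06 to 11.61), PLEKHA3 (6.79 against 7.904 to 8.14), FAM117B (8.28 against 9.16 to 9.69) and CCP110 (8.20 against 8.97 to 9.40). The same held for HSPA14 (9.36 against 10.12 to 10.34), SCML1 (8.10 against 8.80 to 9.22), CKS1B (11.76 against 12.48 to 12.78), CCDC59 (10.57 against 11.26 to 11.45) and USP1 (10.05 against 10.34 to 10.44). KAT2B lay above the others (8.62 against 7.50 to 7.84).

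This array carried the low set of the exon 1 group at the exon 1 level and part of the exon 9 low set. The 95% intervals given here come from resampling the probes of this 1 array and hold no spread between arrays. A wrong label alone would leave the exon 9 set near 0, and its share on the linear scale was 0.464 (95% interval 0.346 to 0.526) against at most 0.222 for another group's set on any other array, which argues against it. A mixture of RNA or cells from both wells would give shares that add to about 1, and they added to 1.499 (1.37 to 1.57), above the highest own share of 1.19 on the other arrays. Uptake of both siRNAs by the same cells is consistent with that exon 9 share together with an exon 1 share of 1.04, although the latter repeats the pattern, and may be tested by transfecting both siRNAs together. Without this array, 433 probes differed between exon 1 and exon 9 against 219 with it.

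The other 11 marks were spread over several groups. Replicate 2 was marked for WLS in the control (11.94 against 11.31 to 11.53), exon 7 (12.02 against 11.33 to 11.54) and exon 9 (12.08 against 11.35 to 11.61) groups, for TMEFF2 in the control (7.70 against 8.25 to 8.58) and exon 1 (8.93 against 9.50 to 9.77) groups, and for ATP9A (9.49 against 8.72 to 8.92) and USP1 (10.85 against 10.44 to 10.56) in the control group. The rest were HMGB2 in control replicate 3 (11.65 against 11.24 to 11.39), SMAP1 in control replicate 5 (7.80 against 8.07 to 8.21), CALU in exon 1 replicate 3 (10.84 against 10.99 to 11.05) and SCML1 in exon 7 replicate 3 (9.36 against 9.73 to 9.92).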

How the results depend on the processing

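The alternatives below that used the intensity set, the probes above the median level, a normexp offset of 16, both the replicate block and an estimated correlation, or that left out the array labelled exon 9 replicate 4 were chosen after the data had been seen. Counts are probes past the adjusted p threshold in the order exon 1, exon 7 and exon 9 against control, exon 1 against exon 7, exon 1 against exon 9, exon 7 against exon 9, exon 1 against the mean of the others, and probes that moved the same way with all 3 siRNAs. With the settings of the report they were 650, 269, 313, 577, 219, 270, 409 and 85 (84 higher and 1 lower). No scaling moved the share of higher calls by over 10 percentage points, but either intensity set taken alone did for several comparisons, such as exon 9 against control (62.3% higher in all arrays, 45.8% in the brighter and 84.4% in the dimmer set). Within a set the groups came from partly different experiments, so these shifts cannot be put down to intensity alone. Detection on all 24 arrays, a slide block and neqc were not run, because the files hold no detection p-values, slides or control probes.

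The replicate block gave 1522, 814, 795, 1525, 746, 1039, 1154 and 203, and with the intensity set added 1769, 964, 959, 1756, 911, 1283, 1408 and 230. Besides the calls given in the report, the replicate block added ATP9A with exon 9 (adjusted p = 0.00707) and changed no other call on a named gene. The brighter set alone gave 133, 13, 59, 68, 85, 37, 107 and 5, and the dimmer set alone 110, 31, 64, 10, 1, 23, 0 (2772 at an unadjusted p under 0.05) and 18, from 3 arrays against 3. A change of at least 1.5-fold left 259, 96, 137, 205, 109, 104, 108 and 35, and an adjusted p below 0.01 left 357, 132, 185, 296, 99, 141, 189 and 55.

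Scaling to the 75th percentile gave 151 with exon 7, 371 between exon 1 and exon 7, 136 between exon 1 and exon 9 and 159 between exon 7 and exon 9. Fitting only the arrays compared gave 173 with exon 7, 76 between exon 1 and exon 9 and 153 between exon 7 and exon 9. Among probes above the median level, adjusted among themselves, the counts were 426 with exon 7, 892, 365 and 474 between siRNAs and 636 for exon 1 against the mean. Leaving out the array labelled exon 9 replicate 4 gave 687, 278, 311, 612, 433, 278, 599 and 79 and a correlation of 0.477 between exon 1 and exon 9, ended the call for MARCKSL1 with exon 1 (adjusted p = 0.0513) and added PTPN14 (0.044) and KAT2B (0.00848) with exon 1. The cause of these differences was not tested.

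Leaving out 1 replicate number at a time gave 358 to 475, 124 to 197, 179 to 237, 277 to 431, 56 to 334, 134 to 205, 133 to 396 and 51 to 74, with the lowest count without replicate 3 each time. Between exon 1 and exon 9, leaving out replicate 4 gave 334. The correlation of fold changes moved between 0.452 and 0.492 (exon 1 and exon 7), 0.483 and 0.578 (exon 1 and exon 9) and 0.455 and 0.506 (exon 7 and exon 9), and was 0.642 for exon 1 and exon 9 in the dimmer set alone. For DIRAS3 the differences from the control ranged from 0.13 to 0.22 with exon 1, from -0.06 to 0.11 with exon 7 and from 0.06 to 0.21 with exon 9. The lists past the threshold numbered 3 to 8 (8 without replicate 2, 3 without replicate 5) against 6, and 17 with the replicate block, 16 with replicate block and intensity set, 10 in the dimmer set alone, and 0 with an estimated correlation, where 5 of 87 had an unadjusted p under 0.05.

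Directions turned for SMAP1 with exon 7 when probes were averaged by gene (0.0221, adjusted p = 0.98), because its 2 probes moved apart. The medians of the S phase list turned to -0.18 with exon 9 in the brighter set and to 0.0299 with exon 1 in the dimmer set, where the groups are not matched by experiment. A normexp offset of 16 ended the calls for PTK2 (adjusted p = 0.0861), MARCKSL1 (0.0947) and PGM2L1 (0.0595) with exon 1, ITGA2 (0.0551) and KAT2B (0.0504) with exon 9, SERPINB3 (0.0755) and HSPA14 (0.065) between exon 1 and exon 9, and the YAP and TEAD list with exon 7 (0.0572).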

Other observations

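In this part the comparison of experiments, and the tests of the control siRNA, the shared target, the intensity sets and the siRNAs' own low sets, were chosen after the results were seen, and the tests of compression and of regrouping before. The 6 experiments differed from each other at 5343 probes (3891 genes), 418 of them by at least 2-fold, averaged over the 4 siRNAs. The 5 named genes with the largest range of experiment means, chosen after the values were seen, were all highest in replicate 2: INHBE (3.80, adjusted p = 2.94e-11), GDF15 (3.66, adjusted p = 5.29e-12), the acute-phase gene ORM1 (3.44), the asparagine synthetase ASNS (3.08) and the stress transcription factor DDIT3 (2.97, adjusted p = 6.78e-13). ASNS and DDIT3 belong to the fixed list of the integrated stress and unfolded protein response, as do CTH (2.86), TRIB3 (2.80) and NUPR1 (2.46) among the 12 largest, while ORM1, IL1A (2.96), S100P (2.80) and others do not. Of the 37 measured genes of that list 27 differed between experiments, with a range of 0.99 in the list mean. Without replicate 2, 2854 probes still differed, and 24 members of that list.

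Replicate 2 also had the highest mean of NF-kappaB targets (range 0.61, 19 of 30 members differing) and of immediate early genes (0.54, 23 of 34), and the lowest means of heat shock proteins (0.64, 11 of 23), hypoxia and glycolysis genes (0.50, 24 of 32), S phase genes (0.52, 29 of 50) and G2 and M phase genes (0.40, 29 of 47). Amino acid or nutrient shortage in that experiment is a hypothesis the labels cannot test, since they give no medium or density for each experiment. The siRNA comparisons draw on all 6 experiments in every group, and with the experiment as a block 1522 probes passed with exon 1, 814 with exon 7 and 795 with exon 9.

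Probes higher with all 3 siRNAs than with the control numbered 84, against 1 lower. A probe lower in the control group than in each other group is the same probe, so the share lower among probes specific to the control (98.8%) restates this count and tests nothing. Whether the single control siRNA lowers these RNAs or loss of GNG12-AS1 raises them could not be told apart, since 3 of the 84 probes differed between siRNAs, which either would allow, and no second control siRNA was used. The intensity sets hold 3 arrays of every group each, so an additive difference between them cancels in each comparison by design, and the 92 probes found with the set as a block are no test of it. PTPMT1 and MET belong to this set, so a second control siRNA is needed before either is tied to GNG12-AS1.

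Probes specific to 1 GNG12-AS1 siRNA were mostly lower: the lowest share was 79.1% (exon 7, 95% interval 63.96 to 89.96). This binomial interval treats probes as independent and holds no spread between arrays or experiments. Of 486 probes lower with any siRNA, 33 were lower with at least 2 (29 of 543 without the array labelled exon 9 replicate 4). The comparisons share their control arrays and sharing by pairs was not simulated, so these counts have no chance value to be read against. Sharing also depended on the fit: probes lower with all 3 siRNAs numbered 1 without a block and 26 with the replicate block. Leaving out probes below the median level took away 1 of 168 specific probes and left 89.2% lower, so it was no test of compression of dim probes at the background, which stays open. That each siRNA lowers RNAs other than its target, such as AKT1 and JOSD1 with exon 7 or FGF2 and MTOR with exon 9, stays a hypothesis, because the share of 79.1% restates the pattern. Isoforms of GNG12-AS1 that contain different exons could also part the siRNAs and were not tested, and the siRNA sequences are not in the sources used here.

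Chance was tested by regrouping arrays, 100 groupings for each result with the real one included. As many probes were called in 1 grouping for exon 1 (650, highest other 2), 1 for exon 9 (313, highest other 10), 1 for exon 1 against exon 7 (577, highest other 5), 1 for exon 7 against exon 9 (270, highest other 22), 1 for exon 1 against the mean (409, highest other 18) and 1 for the shared probes (84, highest other 0). Unlike the real grouping, these broke up the experiments. With groupings that kept the experiments paired, the real one alone called as many, as 1 of 32 for each pair of groups. It was 1 of 50 for exon 1 against the mean and for the shared probes. Chance could be excluded at the resolution of these paired groupings. Among the 100 groupings for exon 7, 2 called as many probes (269, highest other 2253). The other grouping set replicates 1, 4 and 5 against 2, 3 and 6, and with groupings that kept the experiments paired the highest other was 0. Among the 100 for exon 1 against exon 9, 2 called as many (219, highest other 260), where the other grouping was the real one with the array labelled exon 9 replicate 4 and exon 1 replicate 5 exchanged. For the fixed lists 82 of 100 had as many past the threshold (6, highest other 34), but these groupings broke up the experiments, so differences between experiments could enter them. With groupings that kept the experiments paired, 3 of 50 had as many without a block (6, highest other 9, median 1), so chance was not excluded there, and 1 of 50 with the replicate block (17, highest other 16), the real grouping itself.

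The design could separate these hypotheses if a second control siRNA, a probe or PCR for GNG12-AS1 and a rescue were added. For DIRAS3, the gene within GNG12-AS1, the differences from the control were 0.17, 0.02 and 0.12, and 0.10, 0.18 and 0.14 on its second probe. They leave room for a change in intensity of up to 0.40 with exon 1 on the first probe (upper end of the 95% interval). These probes lay at percentiles 61.7 and 40.1 of mean level and no detection filter was applied, so 0.40 is no limit on the RNA itself. The exon 1 values lay between 0.13 and 0.22 as replicates were left out, but had opposite signs in the brighter and dimmer sets. A small rise could neither be shown nor excluded (exact sign-flip p within experiments = 0.125).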
